A study of Homo sapiens with 8 samples.

How the data were processed

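Gene expression was measured in HepG2 cells, an established human liver cancer cell line, on 8 Illumina bead arrays. Per the labels, 4 arrays carried RNA from cells given an siRNA against WEE1 and 4 carried RNA from cells given a negative control siRNA, both at 15 nM and for 48 h. An siRNA is a short double-stranded RNA that directs the cell to degrade a matching messenger RNA, and a negative control siRNA is meant to match none. Per the labels' protocols, column-purified total RNA was checked for quantity and integrity and then amplified into biotin-labelled cRNA, which binds the array's probes. The sources used here give neither the siRNA sequences nor the chip that held each array, and they do not say whether the 4 samples of a group came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical.

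The authors deposited a table with 1 mean probe intensity per probe and array on a linear scale, not normalized between arrays, per the file headers. Beside each intensity the authors deposited a detection p-value, per the file headers. Over all arrays, the smallest detection p-value above 0 was about 1 in 664, which would correspond to a ranking against 664 negative control probes. GenomeStudio 2009.1 is named in the submitters' processing notes. Its settings, the genome build and the probe summary are not given in the sources used here. The authors' processed values of the same arrays, a second deposited table, were also linear intensities. Their column medians were 20.35, 20.39, 20.37 and 20.39 in the negative control arrays and 20.40, 20.44, 20.42 and 20.37 in the WEE1 siRNA arrays. Within each array their ranks equalled those of the non-normalized intensities (Spearman's rho of 1 in 8 of 8 arrays), between 23.7% and 23.9% of them lay below 0, and all 8 columns shared the same lowest and highest values. From the values, they had been background-subtracted and quantile-normalized and had not been centred per gene; which background was subtracted stays unknown. They served only as an alternative.

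The non-normalized intensities were corrected for background, quantile-normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, using the detection p-values and an offset of 16. The offset and the background shrink fold changes of dim probes. Of 24526 probes, 12321 had a detection p-value under 0.05 on at least 4 of the 8 arrays and were kept. Probes carried the gene symbols of the array's design. A table of human RefSeq genes gave 20188 probes a current symbol directly and 3508 through an older symbol, and 823 stayed under the file's symbol. For 7 probes the chromosome in the file contradicted the symbol, among them the probe named for CD24, so these were not matched. Symbols of 39 probes had been turned into dates and were read from the probe's definition. The brightest kept probe stood for each gene, which left 10137 genes. In 34 of the 1741 genes with several kept probes, probes passed the threshold in opposite directions; none of these genes is described by name.

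The groups were compared with limma (lmFit and eBayes, no blocking term), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors are those of limma and intervals are 95% intervals. WEE1 and the principal component scores were also compared by a two-sided exact permutation test over the 70 assignments of 8 arrays to 2 groups, which cannot give a p below 0.0286. Gene lists were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 22 lists that had at least 5 measured members. The result with the correlation estimated from the data is given where it changes a call. Where a gene was below background on all 4 arrays of a group, its fold is a lower bound against the lowest signal detected on those arrays. Where it was below background on only some arrays of a group, no bound was set, and its fold rests partly on background values. The design, the tests, the alternatives, the 24 gene lists and the rule for naming genes were fixed before the data were examined. The rule took WEE1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest adjusted p, and 10 central genes whatever their result. Genes without an established name were not named, and some genes that the rule took were left out of the text without replacement. The exceptions to a list's direction and the genes of the later hypotheses were named after their values were seen.

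The fit was tested on simulated data for this comparison, with 10137 genes, and the observed spread. It recovered 11.9% of 67 genes changed by 0.5 on the log2 scale, 58.2% of 67 changed by 1 and 98.5% of 66 changed by 2, and 9 of its 121 calls were false. In simulated data with 20 lists of 40 genes, camera called the list shifted by -0.5 and 0 of the others. In both simulations the genes were drawn independently of each other and no array deviated. The list test therefore cannot tell how often lists of correlated genes are called falsely. A far smaller share of genes changed there than passed the threshold in the data, and recovery depends on that share. The number of arrays, 4 per group, limits the precision of each value. Between 49.6% and 52.0% of the probes were detected on each array, and the median intensity lay between 159.8 and 195.5. The highest intensity lay between 34616 and 38586.9 in the control arrays and between 52296.5 and 58006.7 in the WEE1 siRNA arrays. As no chip is named, a difference in array processing between the groups cannot be told apart from the siRNA. No 2 arrays held identical values.

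The alternatives were other background corrections and scalings, the authors' processed values, other filters on dim probes, other rules for the probes of a gene, other variance models, array weights, the replicate number as a block, a per-gene test without shared variance, and leaving out each array in turn. For the counts they were a threshold of 1.5-fold and an adjusted p under 0.01, and for the lists an estimated correlation and a rotation test. The estimated correlation without WEE1 siRNA replicate 3 was added after the data had been seen.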

Results

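RNA abundance was profiled in HepG2 cells, an established human liver cancer line, 48 h after transfection with 15 nM of an siRNA against WEE1 or of a negative control siRNA. WEE1 is the kinase that holds CDK1 and CDK2 in check by phosphorylation and so restrains entry into mitosis. The series comprised 8 arrays, 4 per siRNA, and measured 10137 genes above background on at least 4 of them. By its title, the study asked how loss of WEE1 affects tumour growth and stem cell-like traits of liver cancer cells; the arrays address which transcripts differed between the siRNAs.

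WEE1 mRNA was lower in 4 of 4 WEE1 siRNA arrays than in any control array. Its only probe (ILMN_1778561, chromosome 11) had a normalized log2 signal of 9.48 ± 0.20 (SD, n = 4) in the control arrays and 7.54 ± 0.19 (SD, n = 4) in the WEE1 siRNA arrays. The log2 change was -1.93 (SE 0.16, limma adjusted p = 2.01e-05), which left 26.2% of the control level (95% interval 20.5% to 33.4%). The two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 arrays can give. The interval covers the spread between arrays under this processing only, and without background correction the log2 change was -1.39. Before normalization and background correction the signal averaged 824 ± 208 (SD, n = 4) in control and 337 ± 44.3 (SD, n = 4) in WEE1 siRNA arrays.

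The whole profile separated by siRNA. The first principal component held 57.6% of the variance and put the 4 control arrays between -32.03 and -29.80 and the 4 WEE1 siRNA arrays between 21.03 and 42.86 (two-sided exact permutation p = 0.0286). Arrays of the control group correlated across genes at 0.987 to 0.989, WEE1 siRNA replicates 1, 2 and 4 at 0.982 to 0.986, and arrays of different groups at 0.920 to 0.960. WEE1 siRNA replicate 3 correlated with the other WEE1 siRNA arrays at only 0.951 to 0.959 and lay apart on the second component (21.2% of the variance), at -42.3 against 14.9 to 22.7.

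**Figure D1:**
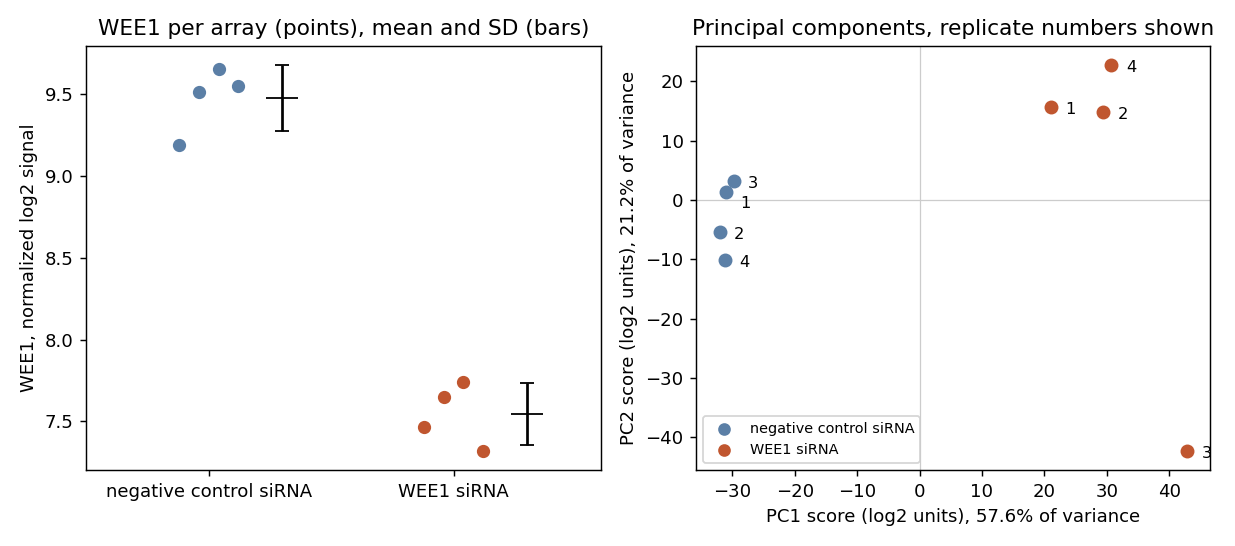
Left, normalized log2 signal of WEE1 in each array (points) with the mean and SD of each group (bars, n = 4); the WEE1 siRNA arrays lie between 7.32 and 7.74 and the control arrays between 9.19 and 9.66. Right, scores of the 8 arrays on the first and second principal components, in log2 units, with replicate numbers; the groups separate on the first component and WEE1 siRNA replicate 3 stands apart on the second.

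Replicate 3 of the WEE1 siRNA group differed from the other 3 in the transcripts of ribosomal proteins, of oxidative phosphorylation and of other small proteins. Relative to the median of all genes, its ribosomal protein transcripts (51 genes) were lower by a median of -0.77 on the log2 scale and those of oxidative phosphorylation (48 genes) by -0.97. The same contrast gave -0.09 to 0.07 for ribosomal proteins and -0.10 to 0.10 for oxidative phosphorylation in the 4 control arrays. A further 76 genes of small proteins stood at -1.11 in this array, and 47 genes of very large proteins at 0.44.

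**Figure D2:**
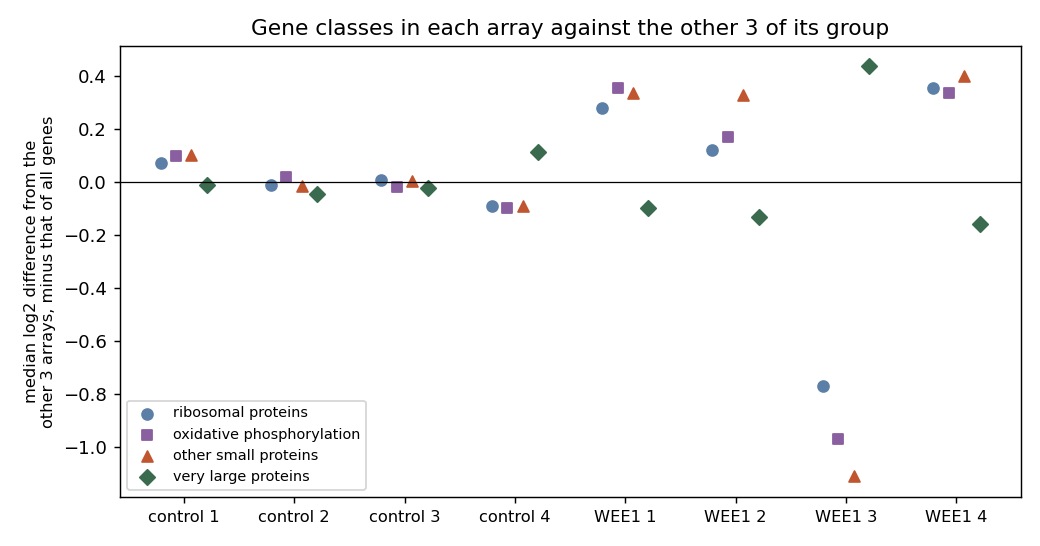
For each array, the median log2 difference from the other 3 arrays of its group, minus that of all genes, for 4 classes of genes (symbols). The control arrays lie near 0. WEE1 siRNA replicate 3 lies at -0.77 for ribosomal proteins, -0.97 for oxidative phosphorylation, -1.11 for other small proteins and 0.44 for very large proteins. The other WEE1 siRNA arrays lie at 0.12 to 0.40 for the first 3 of these classes and at -0.16 to -0.10 for the last. The means against which they are set include replicate 3.

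After WEE1 siRNA, 1732 genes were higher and 1784 were lower by limma, 34.7% of the genes tested, and with median scaling 2081 were higher and 1458 lower. The groups did not overlap in 3107 of these genes. Over all genes, 35.8% had no overlap, against 2.86% by chance. At 2-fold or more, 325 genes rose and 660 fell; the split was 421 to 557 with median scaling, 74 to 284 without background correction, 191 to 487 with an offset of 50 and 517 to 834 in the authors' processed values. Without WEE1 siRNA replicate 3, 2166 genes were higher and 2162 lower, and 3377 calls were shared with the full set of arrays.

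Among the steepest falls were those of SPP1, which encodes the secreted phosphoprotein osteopontin (12.5-fold lower, log2 -3.64, SE 0.19), and CBFB, the partner subunit of the RUNX transcription factors (9.17-fold, SE 0.18). Others were REEP5, a shaper of the endoplasmic reticulum (6.77-fold), the protease inhibitor SERPINE2 (6.01-fold), the mitochondrial ribosomal protein MRPL16 (5.82-fold), the autophagy receptor OPTN (5.76-fold), YPEL5 (5.57-fold), the iron transporter SLC11A2 (5.53-fold), and MRAP and CNN3 (each 5.24-fold). The steepest rise was that of CHGB, the secretory granule protein chromogranin B, which was below background on all 4 control arrays and rose at least 7.67-fold. STOM, encoding the membrane protein stomatin, rose 7.61-fold (SE 0.31), the fibrinogen chain FGB 6.66-fold (SE 0.43), the metalloprotease subunit MEP1A 4.90-fold and the liver transcription factor CREB3L3 4.81-fold. TXNIP, an inhibitor of thioredoxin and glucose uptake, rose 4.04-fold, PDE4C 3.77-fold, the antiproliferative gene BTG2 3.56-fold, LPAR6 3.53-fold, SHBG 3.47-fold, MAPK8IP2 3.45-fold and the CDK inhibitor CDKN1A 3.44-fold. The limma adjusted p of these 22 genes ranged from 1.36e-06 (CHGB) to 9.23e-04 (MRAP). FGB was detected on only 2 of 4 control arrays and MRAP on only 2 of 4 WEE1 siRNA arrays, so their folds rest partly on background values. Without WEE1 siRNA replicate 3 the log2 change of STOM came from 2.93 to 2.58, and that of FGB from 2.74 to 2.38. Those of CBFB and REEP5 grew, from -3.20 to -3.37 and from -2.76 to -2.95. A dimmer probe of MAPK8IP2 read 0.05 (adjusted p = 0.874) and one of CDKN1A read -0.24 (adjusted p = 0.398).

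**Figure D3:**
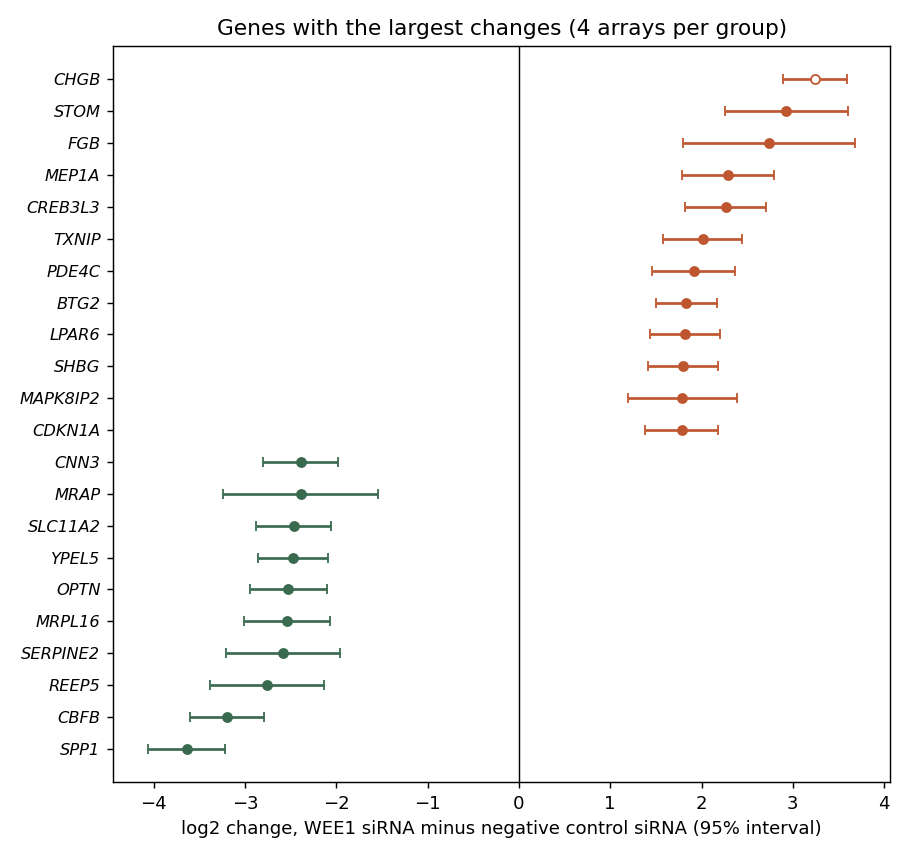
Log2 change (WEE1 siRNA minus negative control siRNA, points) with 95% intervals (bars, 4 arrays per group) of 12 rises and 10 falls among the largest in genes whose groups did not overlap. The changes run from -3.64 for SPP1 to 3.25 for CHGB, whose open symbol marks a control group below background, so that its value is only a fitted one.

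Cell division genes were lower as a group after WEE1 siRNA. Of 52 measured DNA replication genes 32 fell and 2 rose (34 and 2 adjusted over the list alone), with a median log2 change of -0.65 (camera adjusted p = 1.35e-09). RFC5, a subunit of the clamp loader, fell 4.33-fold, the replication initiation factor MCM10 3.88-fold, the nucleotide enzyme DUT 3.58-fold and the ribonucleotide reductase subunit RRM1 2.93-fold. The risers were PRIM2, a primase subunit (log2 1.14), and the ligase LIG1 (0.44). Of 71 mitotic genes 40 fell and 1, KPNA2, rose (43 and 1 adjusted over the list alone; median -0.56, camera adjusted p = 2.04e-09). The adjusted p of this list was 0.0719 with an estimated correlation. PIMREG fell 3.35-fold, the kinetochore gene SKA1 3.17-fold, the kinesin KIF15 2.82-fold and CCNB1, the cyclin B1 that activates CDK1, 2.54-fold. Dimmer probes of DUT and KPNA2 had log2 changes of 0.11 and -0.48, neither past the threshold. The call of KPNA2 was lost without any 1 of 5 arrays (each control replicate or WEE1 siRNA replicate 2; adjusted p up to 0.0799), and that of LIG1 without any 1 of 6 (each array but control replicate 1 and WEE1 siRNA replicate 3; up to 0.107).

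The regulators of CDK1 and CDK2 moved the same way, with 18 of 33 lower and 2 higher (21 and 2 adjusted over the list alone; median -0.54, camera adjusted p = 2.44e-04). CCND3, cyclin D3, fell 3.30-fold and CDK2 1.99-fold, though a dimmer CDK2 probe read 0.49 (adjusted p = 0.0571) and the mean of its probes -0.25 (0.199). CDK1, the main target of WEE1, had a log2 change of -0.39 (SE 0.18, limma adjusted p = 0.123). It passed the threshold without WEE1 siRNA replicate 3 (-0.48, adjusted p = 0.0446), with array weights (-0.47, 0.0391), and with the mean of its probes (-0.65, 0.0217) or the dimmer probe (-0.91, 0.0112). The risers were the inhibitor CDKN1A (log2 1.78, SE 0.18) and CDK7 (0.56), a kinase that activates CDKs. The calls of the DNA replication list and of this list held with an estimated correlation (adjusted p = 0.0341 for both).

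Repair genes of homologous recombination and the Fanconi anaemia pathway were lower too, with 14 of 36 lower and 4 higher (16 and 4 adjusted over the list alone). Their median was -0.41 (camera adjusted p = 0.00716; adjusted p = 0.316 with an estimated correlation). The histone H2AX, which marks broken DNA, fell 2.99-fold, the recombination motor RAD54L 2.07-fold and FANCD2, the monoubiquitinated core of the Fanconi pathway, 2.00-fold. Its dimmer probe read -0.37 (adjusted p = 0.161). The 4 risers were FANCE (1.90-fold), the BRCA2 partner PALB2, the nuclease MRE11 and the helicase BRIP1. The call of MRE11 was lost without control replicate 1 or 3 or WEE1 siRNA replicate 4 (adjusted p up to 0.069) and with its dimmer probe (0.0847). That of BRIP1 was lost without control replicate 2 or 4 or WEE1 siRNA replicate 1, 2 or 4 (up to 0.101) and under 3 of the 4 other scalings. Of 13 measured histone genes 2 fell and 1 rose, the same as adjusted over the list alone (median -0.26, camera adjusted p = 0.401). H4C3 fell 3.70-fold and H2BC21 1.86-fold, the latter not past the threshold in the authors' processed values (adjusted p = 0.119) or in the per-gene test without shared variance (0.0537). H2BC21 was detected on only 2 of 4 WEE1 siRNA arrays. H1-2 had a log2 change of 0.68 (adjusted p = 0.164) and passed the threshold without WEE1 siRNA replicate 3 (1.16, adjusted p = 4.77e-05), in which histone genes were lower than in the other 3 by a median of -0.55. Without that array 3 histone genes rose and 2 fell (median -0.06).

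Targets of the tumour suppressor p53 went both ways. Of 36 measured, 15 rose and 6 fell (16 and 6 adjusted over the list alone), with a median of 0.34 that did not stand apart from other genes (camera adjusted p = 0.269). Besides BTG2 and CDKN1A, the death receptor gene TNFRSF10B rose 2.06-fold and CYFIP2 2.43-fold, although a dimmer CYFIP2 probe read -0.22 (adjusted p = 0.3). MDM2, the ubiquitin ligase that restrains p53, was 1.59-fold higher (adjusted p = 0.0342), a call that ended without control replicate 1, 3 or 4 or WEE1 siRNA replicate 2 (adjusted p up to 0.0863), in the authors' processed values (0.0531) and without a detection filter (0.0513). Its log2 change of 0.67 came to 0.44 without WEE1 siRNA replicate 3. PHLDA3, an inhibitor of AKT, fell 2.64-fold. Of 37 core apoptosis genes 9 rose and 8 fell (10 and 8 adjusted over the list alone), and camera gave an adjusted p of 0.973; the median was 0.07 while the mean of -0.02 and the direction by camera were below 0. The caspase gene CASP2 fell 3.76-fold (dimmer probe -0.57, adjusted p = 0.0679) and BIK, which promotes apoptosis, 2.05-fold, while MCL1, which opposes it, rose 2.81-fold. BIK was detected on only 2 of 4 WEE1 siRNA arrays, so its fold rests partly on background values.

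Among markers used for stem-like liver cancer cells, 5 of 21 measured fell and 2 rose, the same as adjusted over the list alone (median -0.05, camera adjusted p = 0.702). The median was -0.09 without control replicate 3 and -6.86e-04 without WEE1 siRNA replicate 1. PROM1, which encodes CD133, was 2.50-fold lower (log2 -1.32, SE 0.33, limma adjusted p = 0.00938; 0.0608 in the per-gene test without shared variance). ALDH1A1 was 2.26-fold and the progenitor factor SOX9 1.72-fold lower. The other falls were those of TWIST1 (log2 -0.62) and LIN28B (-0.69), and the rises those of HMGA2 (2.02-fold) and CTNNB1 (0.75). HMGA2 was detected on only 2 of 4 control arrays, and its groups overlapped. LIN28B lost its call without control replicate 1 or 4 or WEE1 siRNA replicate 1, 2 or 4 (adjusted p up to 0.0736), with median scaling (0.0595) and in the per-gene test without shared variance (0.0683), TWIST1 without control replicate 3 (0.0507), and CTNNB1 without any 1 of 6 arrays (each control replicate and WEE1 siRNA replicates 2 and 4; up to 0.11), in the authors' processed values (0.0747) and without a detection filter (0.0765). CTNNB1 came to 0.45 without WEE1 siRNA replicate 3, in which the listed markers were higher than in the other 3 by a median of 0.42. EPCAM had a log2 change of -0.31 (SE 0.24, adjusted p = 0.349; -0.15 without control replicate 4 and -0.09 without WEE1 siRNA replicate 2), and AFP, the fetal liver protein, one of 0.40 (SE 0.15, adjusted p = 0.0553). AFP passed the threshold under 8 alternatives, among them without WEE1 siRNA replicate 3 (0.30, adjusted p = 0.0439) and with median scaling (0.72, 0.00342). CD44 and THY1 were above background on 0 of 8 arrays.

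Of 44 mature hepatocyte genes 8 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.10, or 0.06 without WEE1 siRNA replicate 2 and 0.16 without WEE1 siRNA replicate 4, camera adjusted p = 0.401), and without WEE1 siRNA replicate 3, 9 rose and 5 fell. All 3 fibrinogen chain genes rose, FGB with a log2 change of 2.74, FGG 1.75 and FGA 1.35, as did the plasma protein FETUB (2.31-fold) and CYP1A1 (2.44-fold). Among the falls were the liver transcription factors FOXA2 (-0.70) and NR1I2 (-0.56). The FOXA2 call was lost without control replicate 3 or WEE1 siRNA replicate 4 (adjusted p up to 0.0521), and that of NR1I2 without control replicate 1 or 2 (up to 0.0597). Median scaling also ended the call of FOXA2 (0.0612), and the lack of background correction that of NR1I2 (-0.20, adjusted p = 0.0804). ALB, the albumin gene, had a log2 change of -0.28 (SE 0.14, adjusted p = 0.142), which was 0.05 with median scaling and passed the threshold without background correction (-0.27, adjusted p = 0.0465).

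Genes of ribosome biogenesis and MYC targets were higher as a group, with 13 of 42 higher and 2 lower, the same as adjusted over the list alone (median 0.23, camera adjusted p = 0.0152). The adjusted p was 0.562 with an estimated correlation, 0.0721 without WEE1 siRNA replicate 3 and 0.0507 without WEE1 siRNA replicate 4. Without either array UTP20, below background on the control arrays, no longer passed the detection filter. This left 41 measured genes without replicate 3, so the list itself also differed there. UTP20 rose at least 2.54-fold from below background and the RNA polymerase I subunit POLR1A 2.77-fold, while PA2G4 (1.84-fold) and PES1 (log2 -0.85) fell.

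No list of metabolic genes passed the threshold. Of 21 cholesterol synthesis genes 6 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 0.269), and without WEE1 siRNA replicate 3, 7 rose and 2 fell. The sterol oxidase gene MSMO1 rose 1.78-fold, though its dimmer probe read 0.46 (adjusted p = 0.203), while ACAT2 fell 2.57-fold. Of 19 genes of fatty acid and triglyceride synthesis 3 rose and 7 fell (3 and 8 adjusted over the list alone; median -0.12, camera adjusted p = 0.401). This median was -0.25 without control replicate 2 and -0.39 without WEE1 siRNA replicate 2. MLXIPL, which encodes the glucose-responsive factor ChREBP, rose 3.42-fold and the elongase ELOVL6 2.33-fold; the desaturase FADS1 fell 2.02-fold and GPAM 2.29-fold. Of 27 glycolysis and hypoxia genes 4 rose and 8 fell, the same as adjusted over the list alone (median -0.25, camera adjusted p = 0.349). The glycolytic regulators PFKFB3 and PFKFB4 fell 2.10-fold and 2.09-fold, and VEGFA rose 2.46-fold (dimmer probe 0.58, adjusted p = 0.0525); the list's median was -0.15 without WEE1 siRNA replicate 3. Of 48 oxidative phosphorylation genes 3 rose and 8 fell (2 and 7 adjusted over the list alone; median -0.22, camera adjusted p = 0.269), and without WEE1 siRNA replicate 3, 7 rose and 9 fell (median -0.07). NDUFA10 rose 2.91-fold; COX7C had a log2 change of -1.69, or -1.30 without that array, and NDUFC1 one of -1.64, or -1.23. In that array the genes of fatty acid and triglyceride synthesis were higher than in the other 3 by a median of 0.30.

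Stress and inflammatory genes also went both ways. Of 34 genes of the unfolded protein response and ATF4, 8 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.11, camera adjusted p = 0.428). HERPUD1 rose 2.17-fold and TRIB3 1.88-fold, and STC2 fell 1.79-fold; in WEE1 siRNA replicate 3 this list was higher than in the other 3 by a median of 0.28. The list's median was 0.07 without control replicate 2 or WEE1 siRNA replicate 2, 0.05 without WEE1 siRNA replicate 3, where 10 rose and 6 fell, and 0.02 without WEE1 siRNA replicate 4. Of 27 heat shock and immediate early genes 3 rose and 5 fell, the same as adjusted over the list alone (median 0.06, camera adjusted p = 0.849). This median was 0.02 without control replicate 1 and 0.12 to 0.20 without control replicate 2 or 3 or any 1 WEE1 siRNA array, and 5 rose and 5 fell without WEE1 siRNA replicate 3. The chaperone gene HSPA1B fell 3.20-fold and EGR1 rose 1.81-fold. Of 14 inflammatory and NF-kB genes 6 rose and 2 fell, the same as adjusted over the list alone (median 0.23, camera adjusted p = 0.349). The fallers were HAMP, encoding the iron hormone hepcidin (5.22-fold, SE 0.46), and the chemokine CXCL8 (2.56-fold), and SOD2 rose 2.20-fold. Of 22 interferon response genes 4 rose and 4 fell, the same as adjusted over the list alone (median -0.25, camera adjusted p = 0.428); IRF1 fell 2.03-fold and IFIT3 rose at least 1.34-fold. Without WEE1 siRNA replicate 3, 2 of 21 interferon response genes rose and 5 fell (median -0.14), IFIT3 no longer passing the detection filter. Of 9 genes of the RNA interference pathway 2 rose and 3 fell (4 and 4 adjusted over the list alone). Their median was 0.23 (0.11 without WEE1 siRNA replicate 3, with 4 higher and 4 lower) while their mean was -0.23 and the direction by camera was down (adjusted p = 0.876). DGCR8, a subunit of the microRNA processor, fell 2.62-fold and AGO1 2.05-fold. Of 21 genes of the epithelial to mesenchymal transition 2 rose and 5 fell (4 and 5 adjusted over the list alone; median -0.05, camera adjusted p = 0.973). TJP1, a tight junction gene, fell 3.06-fold, and KRT18 rose 2.00-fold. S100A4 was at least 1.64-fold lower, with its WEE1 siRNA arrays below background. Without any 1 of the 4 control arrays that probe was no longer kept, and another S100A4 probe gave -0.27 to -0.39, not past the threshold; the call also ended in the authors' processed values (adjusted p = 0.219).

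**Figure D4:**
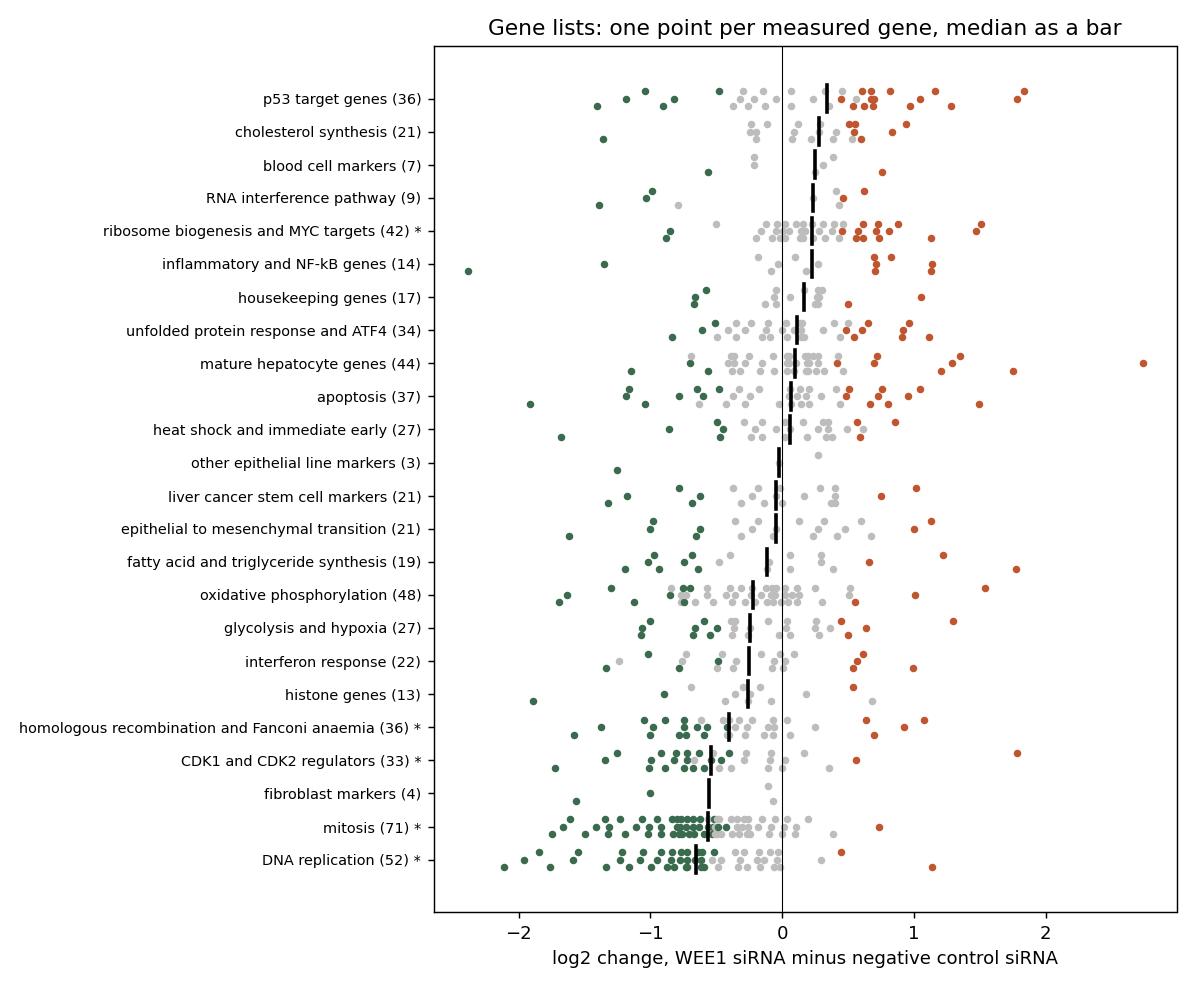
Log2 change of each measured member (points) of the 24 gene lists, with members past the threshold in colour, the list median as a bar and the number of measured members in parentheses. Asterisks mark the 5 lists past the threshold by camera at the preset correlation, 4 of them shifted down and 1 up. With an estimated correlation the calls ended for mitosis (camera adjusted p = 0.0719), homologous recombination and Fanconi anaemia (0.316) and ribosome biogenesis and MYC targets (0.562).

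Markers of other cells were mostly below background. Of 14 fibroblast markers 4 were measured, of which PDGFRB (2.96-fold) and S100A4 fell, and PDGFRA and TAGLN had log2 changes of -0.11 and -0.07. Of 15 markers of other epithelial lines 3 were measured, of which SFN fell 2.38-fold; both lists were too short to test, and adjustment over the list alone gave the same counts. Of 7 measured blood cell markers LYZ was 1.69-fold higher and LCP1 1.48-fold lower (log2 -0.19, adjusted p = 0.0732 without background correction), the same as adjusted over the list alone (median 0.25, camera adjusted p = 0.876). Of 17 housekeeping genes 2 rose and 3 fell, the same as adjusted over the list alone (median 0.16, camera adjusted p = 0.626), among them RPL13A (2.08-fold higher) and PGK1 (1.59-fold lower). In WEE1 siRNA replicate 3 the blood cell markers were lower than in the other 3 by a median of -0.53 and the fibroblast markers by -0.58; without it 2 blood cell markers rose and 1 fell.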

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

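The tests of a swap and of a dimmer array for WEE1 siRNA replicate 3 were chosen after their results had been seen; those on the number of genes and on small proteins were written first, the latter after values of ribosomal and oxidative phosphorylation genes in that array had been seen.

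In 290 groups of 4 arrays, 1 array lay far from the other 3 in 18, where chance alone gives about 14.5, and 10 of the 18 were in WEE1 siRNA replicate 3. On the second principal component that array scored -42.3 against 14.9 to 22.7 in the other 3. Its log2 signals above those of the other 3 were AFP 15.1 (14.6 to 14.7), CNN3 9.73 (8.98 to 9.09), CTNNB1 11.9 (10.6 to 10.7), CYFIP2 12.5 (11.9 to 12.0), FGA 13.3 (12.0 to 12.2) and HERPUD1 12.1 (all 11.4). Those below were H1-2 7.34 (9.13 to 9.26), IFI35 8.25 (8.983 to 9.001) and S100A2 6.13 (6.24 to 6.26).

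In the other WEE1 siRNA arrays, replicate 1 stood apart in POLR1A at 6.77 (7.64 to 7.76 in the other 3), replicate 2 in RFC5 at 8.41 (8.67 to 8.70) and YPEL5 at 6.66 (7.24 to 7.35), and replicate 4 in EGR1 at 9.67 (9.23 to 9.28). Of the control arrays, replicate 2 stood apart in STOM at 7.37 (7.02 to 7.06), replicate 3 in PDGFRB at 8.05 (7.36 to 7.40), and replicate 4 in H3C10 at 6.78 (6.41 to 6.45) and LYZ at 7.25 (7.77 to 7.82).

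In WEE1 siRNA replicate 3, 978 genes differed at least 2-fold from the mean of the other 3, against 20 to 26 in the control arrays and 30 to 120 in the other WEE1 siRNA arrays. The means against which those other WEE1 siRNA arrays were set included replicate 3, which can raise their counts. A swap with a control array was argued against by WEE1, which lay -1.45 below the lowest control array (control SD 0.20), and a dimmer array by its 52.0% of probes detected, against a median of 50.2% over the 8 arrays. A lower yield of short messages in that array may account for the pattern: genes of small proteins outside the ribosomal and oxidative phosphorylation lists stood at -1.11 relative to all genes, and genes of very large proteins at 0.44. Whether this arose in the RNA, the labelling or the culture stays open, and no biological explanation was tested, since the labels give the 4 arrays the same treatment.

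The division of the arrays by siRNA gave 3516 genes past the threshold by limma, and of the 35 divisions of the 8 arrays into 4 and 4 only 1, the real one, gave as many. The highest other count was 0, and 1387 against 4533 for the real one at an unadjusted p under 0.05. Chance can be excluded only as far as 1 of 35 divisions allows, and the other divisions carry the difference between the siRNAs in their spread, which lowers their counts. Effects of the siRNA on messages other than WEE1 were not tested, since the sources used here give no siRNA sequence.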

How the results depend on the processing

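The estimated correlation without WEE1 siRNA replicate 3 was added after the data had been seen; the other alternatives were not. WEE1 was lower and past the threshold in each alternative (log2 -2.10 to -1.39; adjusted p up to 8.40e-04). Of 140 other named genes 129 were past the threshold. Of these, 124 kept their direction and 99 also the threshold under every alternative in which they were measured. Genes below background on every control array, such as CHGB, did not pass the detection filter in some alternatives. At an adjusted p under 0.01, 895 genes were higher and 1120 lower. The numbers of higher and lower genes ran from 1275 to 2166 and from 1405 to 2162 when 1 array was left out. With the replicate number as a block they were 1390 and 1520, WEE1 was at -1.93 and GAPDH and LIG1 were no longer past the threshold. No block by chip was run, as no chip is named. Array weights gave WEE1 siRNA replicate 3 a weight of 0.161, against 0.850 to 1.77 for the others, with 2293 genes higher and 2279 lower. The signal over background limits dim genes: 7332 genes were detected at a p under 0.01 on all 8 arrays, of which 1489 were higher and 1390 lower. Except where said, the cause was not tested.

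With an estimated correlation the calls of mitosis (median -0.56), homologous recombination and Fanconi anaemia (-0.41) and ribosome biogenesis and MYC targets (0.23) ended. Without WEE1 siRNA replicate 3 as well, these stood at -0.57 (camera adjusted p = 0.155), -0.38 (0.543) and 0.20 (0.554). The median of ribosome biogenesis and MYC targets ran from 0.20 to 0.27 when 1 array was left out. Its call was lost without WEE1 siRNA replicate 3 (camera adjusted p = 0.0721) or 4 (0.0507), where UTP20 did not pass the detection filter. The rotation test, which asks whether a list changed at all and not whether it changed more than other genes, also called p53 target genes (0.34), mature hepatocyte genes (0.10), inflammatory and NF-kB genes (0.23) and glycolysis and hypoxia (-0.25).

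Lists without a call turned direction by camera as follows, given as medians. For the epithelial to mesenchymal transition these were -0.0207 without background correction, -0.0403 with an offset of 50, 0.0634 with median scaling, -0.0577 in the authors' values, 0.0267 without a detection filter, and -0.0501 with the strict filter. Over the 8 settings that leave out 1 array its medians ran from -0.10 to 0.14, and the direction turned without any 1 control array or WEE1 siRNA replicate 4. Apoptosis had 0.12 without a filter, 0.0926 with the strict filter, 0.12 with the mean and 0.14 with the dimmest probe. With 1 array left out its medians ran from 0.0120 to 0.15, and the direction turned without control replicate 1, 2 or 3 or WEE1 siRNA replicate 2. The RNA interference pathway had 0.0815 without a filter and 0.41 with the strict filter, and blood cell markers had -0.0167 without a filter. With 1 array left out the medians of blood cell markers ran from 0.14 to 0.34, and the direction turned only without WEE1 siRNA replicate 4 (0.14). Those of histone genes ran from -0.39 to -0.0590, and the direction turned only without WEE1 siRNA replicate 3 (-0.0590, with the preset and with an estimated correlation). The per-gene test without shared variance ended the calls of H2BC21, PROM1, TNRC6B, MDM2, KPNA2, MRE11, BRIP1, PES1, CTNNB1, LIN28B and FOXA2 (adjusted p up to 0.135, for CTNNB1). Among genes, median scaling turned ALB (0.0488), TAGLN (0.0634) and S100A2 (0.0381), and array weights TAGLN (0.15). The dimmest probe turned CDKN1A (-0.24), CDK2 (0.49), CYFIP2 (-0.22), DUT (0.11) and KPNA2 (-0.48). Leaving out 1 array gave S100A2 -0.11 to 0.0359, PDGFRA -0.28 to 0.0521 and TAGLN -0.18 to 0.17.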

Other observations

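The tests of the 4 sets of target genes and of the 2-fold falls were chosen after the gene values had been seen, each being written down before its own result was seen, except that the value of HMOX1 among the NRF2 targets was already known. The genes named here were chosen after their values were seen.

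Genes of xenobiotic and oxidant defence were among the stronger falls after WEE1 siRNA. AKR1B10, an aldo-keto reductase, had a log2 change of -2.13 (limma adjusted p = 9.38e-06) and the glutathione transferase GSTA2 one of -2.25 (1.39e-05). Both are targets of NRF2, a transcription factor of the oxidant response. Of 26 other measured NRF2 targets 8 fell and 2 rose, the same as adjusted over the list alone, with AKR1C2 at -1.69, TXNRD1 at -1.41 and NQO1 at -1.39 among the falls. PGD, an enzyme of the pentose phosphate pathway, was among the rises (0.74). The set without AKR1B10 and GSTA2 may have been lower as a whole, with a median of -0.26 (camera adjusted p = 0.0203 over the 5 later sets; adjusted p = 0.317 with an estimated correlation).

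HAMP, which BMP signals induce through SMAD proteins in hepatocytes, fell 5.22-fold (log2 -2.39, SE 0.46). Its WEE1 siRNA arrays spread from 8.85 to 11.5 on the log2 scale, against 12.0 to 12.6 in the control arrays. Of 11 other measured BMP and SMAD targets 7 fell and 0 rose, the same as adjusted over the list alone; at an unadjusted p under 0.05 the set still held no rise by limma. SMAD9 was at -1.91, ID3 at -1.28 and ATOH8 at -1.28. Among the 4 not past the threshold were ID1 at -0.49 (limma adjusted p = 0.0902) and ID2 at -0.03. A lower output of this pathway may be part of the response, as the set had a median of -0.65 (camera adjusted p = 0.00428; adjusted p = 0.13997 with an estimated correlation).

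Hypotheses on 2 other pathways stayed open. TXNIP and MLXIPL were among the strong rises, and the other targets of ChREBP, the factor encoded by MLXIPL, had a median of 0.0576 over 15 genes, or -0.0587 without WEE1 siRNA replicate 3. Of these 4 rose and 2 fell, the same as adjusted over the list alone (camera adjusted p = 0.784), with ELOVL6 at 1.22 and the glucose transporter SLC2A2 at -1.80. Of 14 measured Wnt targets, a set chosen because of SPP1, 5 fell and 2 rose, the same as adjusted over the list alone, with a median of -0.0631, or -0.0950 without WEE1 siRNA replicate 3 (camera adjusted p = 0.422); TNFRSF19 was at -1.74 and CCND1 at -0.81. Of 51 ribosomal protein genes 2 rose and 2 fell (1 and 1 adjusted over the list alone; median -0.07, or 0.14 without WEE1 siRNA replicate 3, camera adjusted p = 0.867 over the 5 later sets).

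Falls of at least 2-fold outnumbered rises by a ratio of 2.03. The ratio was 2.22 without WEE1 siRNA replicate 3 and 1.95 without the 5 lists of cell division and repair genes, which held 33 of the falls and 3 of the rises, so neither the array nor these lists can be the whole origin. The scaling stays open: the ratio ran from 1.32 with median scaling to 3.84 without background correction, and which scaling is closer to the cells' RNA cannot be told apart here. Effects of the siRNA on messages other than WEE1, which were not tested, stay open too. So does a difference in array processing between the groups, whose highest non-normalized intensities did not overlap. In 4 equal classes of genes by brightness, from dim to bright, 116, 204, 203 and 137 genes fell and 71, 114, 97 and 43 rose at least 2-fold.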
